A study of Mus musculus with 6 samples.

How the data were processed

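The samples were pieces of lesional skin from mice with a psoriasis-like disease that had received regulatory T cells (Tregs) by transfer. The cells were either control Tregs (Ctrl-Treg) or Tregs exposed to lenvatinib (Lenv-Treg), an inhibitor of receptor tyrosine kinases that include the VEGF and FGF receptors. There were 6 RNA-seq libraries, 3 per group, and the treatment label of each sample set its group. Per the labels' protocols, total RNA was extracted with TRIzol, its integrity was assessed on a Bioanalyzer, and libraries were made with a VAHTS Universal V10 kit. The labels do not state whether the 3 samples of a group came from separate mice, so p-values measure the spread between these samples, which may in part be technical.

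The values used were FPKM (fragments per gene, divided by gene length and by library depth) as deposited by the authors, in 1 table of 35434 gene symbols by 6 samples. The genome build was GRCm39, per the submitters' processing notes. The aligner, the counting tool, the annotation and any filter are not given in the sources used here. The reference annotation used here was of another build, so no coordinates are given. All 6 columns matched a sample title, and no other column of sample values was present.

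Low FPKM values of a gene were whole multiples of 1 step, which allowed depth to be recovered. The constant that linked step and gene length was taken from 238 genes whose reference length matched it, among 6822 genes with low values and a reference length. Assigned reads per sample then came to 38704536 to 40248462, a ratio of 1.04 between the deepest and the shallowest library. With a tolerance of 0.005 reads plus 1.5e-07 per read, 13944 of the 13945 genes passing the filter gave whole reads in all 6 samples. The recovered reads summed to between 99.61% and 99.7% of the depth in each sample. Tested on simulated data of 1883 genes, the procedure returned the exact reads for 99.36% of genes. At these depths 1 read on a gene of 1 kb was worth 0.0248 to 0.0258 FPKM. Where a group had no read of a gene, a floor of 3 reads over the group was used, and such floors cover counting error only.

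Genes with an FPKM of at least 0.5 in at least 3 of the 6 samples were tested, 13945 in all. The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on log2(FPKM + 1), without covariates, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are Lenv-Treg minus Ctrl-Treg on the log2(FPKM + 1) scale, which understates the change of genes with low values. Group values are mean FPKM ± SD with n = 3, and folds are ratios of mean FPKM. An exact permutation test of 3 against 3 samples cannot go below p = 0.1, and it is given only for single genes outside the filter.

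There were 35 gene lists (904 genes, of which 881 were named in the table and 803 tested), covering inflammation, epidermis, immune and other cell types, metabolism and RNA handling. Mitochondrially encoded genes were matched to the table's own names after these were seen. Lists with at least 5 tested members were compared with all other tested genes by limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 35 lists. Camera with an estimated correlation and fry, which tests each list on its own, were alternatives. The groups, the test, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated.

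Genes were named by a rule with 3 parts. The first part took, per direction, the 12 genes with the largest difference among those past the threshold whose groups did not overlap, leaving out predicted genes, pseudogenes and receptor or immunoglobulin segments. The second part took up to 4 members of each list past the threshold and of each list on inflammation, epidermis or regulatory T cells: the 2 with the highest mean FPKM and the 2 others with the smallest p. The third part was a set of 25 single genes, reported whatever their result. Families of near-identical genes (Sprr2, the stefin genes, Lce3, Krtap and Skint) are uncertain gene by gene, since reads could be shared between copies.

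Tested on simulated reads for this comparison, in 13735 genes with real means, spreads and depths, limma recovered 12.2% of genes changed by 0.5 on the log2 scale, 62% of those changed by 1, 92% of those changed by 2 and 94% of those changed by 4. Of its calls, 6.47% were false. Only 49 or 50 genes were changed at each size, while 41.7% of the real tested genes passed. These rates may therefore differ in the real comparison. Alternatives covered the pseudocount (0.1 and 0.5), the filter, the scaling between samples, the variance model, sample weights, the replicate number as a block, leaving out each library, the list test and the threshold. Limma's voom on the recovered reads was added after the data were seen. Tested genes were held fixed when scaling was changed or a library was left out.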

Results

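RNA-seq of lesional skin compared mice given control Tregs with mice given lenvatinib-treated Tregs, 3 libraries per group. Depth was similar in all libraries, at 40247457, 39163353 and 38704536 assigned reads in Ctrl-Treg and 39974310, 40248462 and 39606294 in Lenv-Treg, as recovered from the FPKM values. No gene in the table marks which cells a mouse received, so groups below are those of the libraries labelled Ctrl-Treg and Lenv-Treg. The series title attributes a stronger anti-inflammatory effect to lenvatinib-treated Tregs, and the comparison asks how the skin transcriptome differed between the treatments. All 6 libraries had the expression pattern of male mice, with Xist at no more than 0.00144 FPKM and Ddx3y between 9.95 and 27.7 FPKM.

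The libraries separated by group. The first principal component held 84.6% of the variance and placed the Ctrl-Treg libraries between -52.2 and -37 and the Lenv-Treg libraries between 39.1 and 50.4. Pearson correlations across genes were 0.984 to 0.992 within groups and 0.897 to 0.939 between groups. No pair of libraries agreed within sampling noise.

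**Figure D1:**
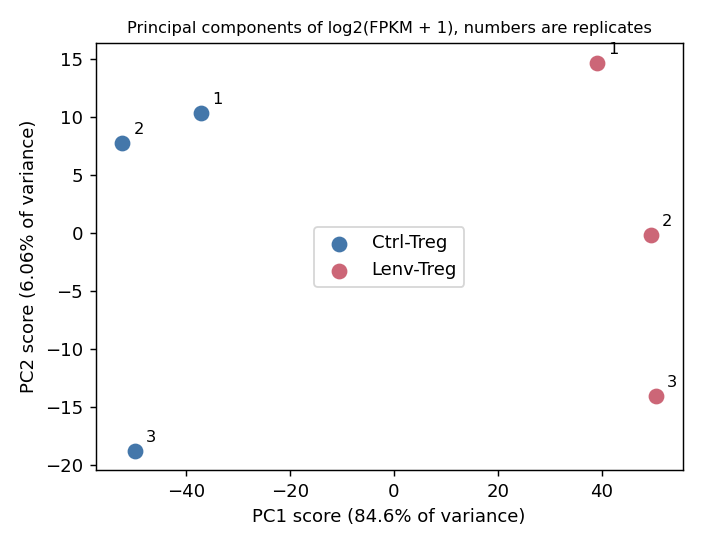
Scores of the 6 libraries on the first and second principal components of log2(FPKM + 1), in arbitrary units, coloured by group and numbered by replicate. The groups lie on opposite sides of the first component, which held 84.6% of the variance.

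Of 13945 genes tested, 5821 passed the threshold in limma (41.7%), 1532 higher and 4289 lower in the libraries labelled Lenv-Treg. At a difference of at least 2-fold, 524 were higher and 816 lower. The median difference of all tested genes was -0.17. After scaling to equal medians of ratios, which centres the differences (median 0.00), 2417 genes were higher and 2417 lower, a balance largely set by that centring. With the values rescaled to TPM, 947 were higher and 7970 lower, with a median of -0.44. The values do not say which scaling holds, so the balance of higher and lower genes is left open, and list medians are given below with their value after median-ratio scaling (scaled) and, where it moved by over 1.5 times in a list that passed, after rescaling to TPM (TPM). Groups did not overlap for 55.4% of tested genes, against 10% by chance.

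The 12 genes with the largest increases in the libraries labelled Lenv-Treg included both calprotectin genes. S100a8 and S100a9, which encode its subunits, rose from 46.9 ± 32.9 to 21890 ± 3885 FPKM (log2 difference 9.09, SE 0.51, adjusted p = 4.05e-05) and from 56.3 ± 37.9 to 24390 ± 4081 FPKM (8.92, SE 0.43, adjusted p = 2.91e-05). Together they took 1.75% to 2.46% of reads in Lenv-Treg and 0.00208% to 0.00841% in Ctrl-Treg. Cxcl2, a neutrophil-attracting chemokine, rose from 0.844 ± 0.970 to 444.7 ± 152.6 FPKM (7.98, SE 0.39). The other 9 of the 12 were Csta3, a stefin gene, 213-fold higher, and, by log2 difference, Sprr2b (7.98), Krt6b (7.88), Defb3 (7.54), Sprr2i (7.26), Sprr2d (6.98), Sprr2e (6.79), Cxcl3 (6.66) and Sprr2f (6.60). The Sprr2 genes encode small proline-rich proteins of the cornified envelope, and Defb3 encodes a beta-defensin. Adjusted p over the 12 genes reached at most 0.00124, for Krt6b. For all 12, leaving out 1 Ctrl-Treg library (replicate 2 for Cxcl2 and Cxcl3, replicate 1 for the others) raised the fold of mean FPKM by over 1.5 times, from 1.58 times for Sprr2e to 9.11 times for Krt6b (94.9-fold to 865-fold). Without that library the fold was 800 for Csta3, 746 against 467 for S100a8 and 699 against 433 for S100a9.

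Genes on the lists of the psoriatic and wound response of keratinocytes rose as groups. Of 32 tested members of the list of keratinocyte responses to IL-17 and psoriasis genes, 30 rose and 0 fell, 31 and 0 when adjusted over the list alone (median 2.76, scaled 2.96). Neutrophil genes rose in the same libraries (20 of 23, median 2.46), and neutrophils also express members of this list such as S100a8, S100a9, Lcn2, Stfa1 and Stfa3. Lcn2, which encodes an iron-sequestering antimicrobial protein, rose from 13.4 ± 7.0 to 1107 ± 432.1 FPKM, and the defensin Defb4 from 0.167 ± 0.169 to 63.4 ± 15.8 FPKM (379-fold, and 779-fold without Ctrl-Treg replicate 3). In the list of wound keratins and SPRR genes, 19 of 22 rose and 1 fell, also when adjusted over the list alone (median 4.12, scaled 4.27). Krt16 and Krt6a, keratins of activated epidermis, rose 44.7-fold (108-fold without Ctrl-Treg replicate 1) and 32.9-fold. Krt17, another keratin of activated epidermis, was 468.6 ± 65.4 FPKM in Ctrl-Treg and 491.0 ± 159.1 FPKM in Lenv-Treg (adjusted p = 0.93). Camera placed both lists above other genes (adjusted p = 1e-27 and 9.3e-20). With an estimated correlation, which ended the call of every list in the report, adjusted p = 0.19 for each.

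Cytokine and chemokine genes rose as well. The type 17 list shares Il17c, Il19 and Il24 with the keratinocyte response list. The chemokine list shares Cxcl1, Cxcl2, Cxcl3, Cxcl5 and Ccl20 with it. In the type 17 list 13 of 23 members rose and 2 fell, also when adjusted over the list alone (median 0.42, scaled 0.61, 0.64 after quantile normalization, camera adjusted p = 3.7e-06, adjusted p = 0.19 with an estimated correlation). Il17a was 0.0288 ± 0.0118 FPKM in Ctrl-Treg, from 4 reads over the group, and 1.79 ± 1.38 FPKM in Lenv-Treg (log2 difference 1.33, SE 0.30, adjusted p = 0.0105), a fold of 62.1 that was 34.8 without Lenv-Treg replicate 3. Il17f rose 49.4-fold to 4.64 ± 2.63 FPKM (118-fold without Ctrl-Treg replicate 1), and Il17c 35.5-fold to 1.28 ± 0.229 FPKM. Il22 had 0 reads in Ctrl-Treg and 2.21 ± 1.53 FPKM in Lenv-Treg, at least 120-fold higher against a floor of 3 reads over the group (adjusted p = 0.00409). That limit was 73.7-fold without Lenv-Treg replicate 3 and 80.4-fold without Ctrl-Treg replicate 1. Stat3 rose by 0.76, and Maf did not pass (-0.13, adjusted p = 0.351). Il23a lay outside the filter, at 0.0441 ± 0.0392 and 0.751 ± 0.430 FPKM, a fold of 17.1 that was 26.3 without Ctrl-Treg replicate 2 (exact permutation p = 0.1, the smallest possible). In limma with no filter on low values it passed (0.72, adjusted p = 0.032), from 7 and 122 reads over the groups. Foxp3 (adjusted p = 0.28) and Ifng (adjusted p = 0.2), also outside the filter, did not pass in that fit.

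In the list of TNF, IL-1 and NF-kB genes, 25 of 34 rose and 1 fell, 26 and 1 over the list alone (median 1.1, scaled 1.29, camera adjusted p = 1.6e-16, adjusted p = 0.19 with an estimated correlation). Il1b rose from 4.78 ± 1.39 to 313.2 ± 105.2 FPKM (5.72, SE 0.28), Tnf 3.97-fold, Il6 14.1-fold (39.9-fold without Ctrl-Treg replicate 1), and Mmp3, a matrix metalloproteinase, 4.9-fold. Vcam1 (1.73) and Plaur (2.76) rose too. Of 31 chemokines, 18 rose and 5 fell, also over the list alone (median 1.02, scaled 1.23, camera adjusted p = 2.7e-07, adjusted p = 0.19 with an estimated correlation). Cxcl1 rose 24.5-fold (43.6-fold without Ctrl-Treg replicate 1 and 15.2-fold without Lenv-Treg replicate 3), Ccl6 8.43-fold and Ccl20, a ligand of CCR6, 2.2-fold, while Ccl8 did not pass (0.42, adjusted p = 0.187). Neutrophil genes (20 of 23, median 2.46) and macrophage genes (19 of 31, median 0.75) rose in the same libraries, and the values do not say in which cells cytokine and chemokine genes were higher. Type 2 genes were mixed: 6 of 15 rose and 3 fell, 7 and 3 over the list alone (median 0.32, scaled 0.42, TPM 0.13, 0.50 after quantile normalization, camera adjusted p = 0.0016, adjusted p = 0.19 with an estimated correlation). Il33 rose 11.2-fold and Chil3 88.9-fold, and Retnla fell by 2.15. The cytokine genes Il4, Il5, Il13, Il25 and Il31 and the genes Epx, Prg2, Siglecf and Ccr3 lay outside the filter.

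**Figure D2:**
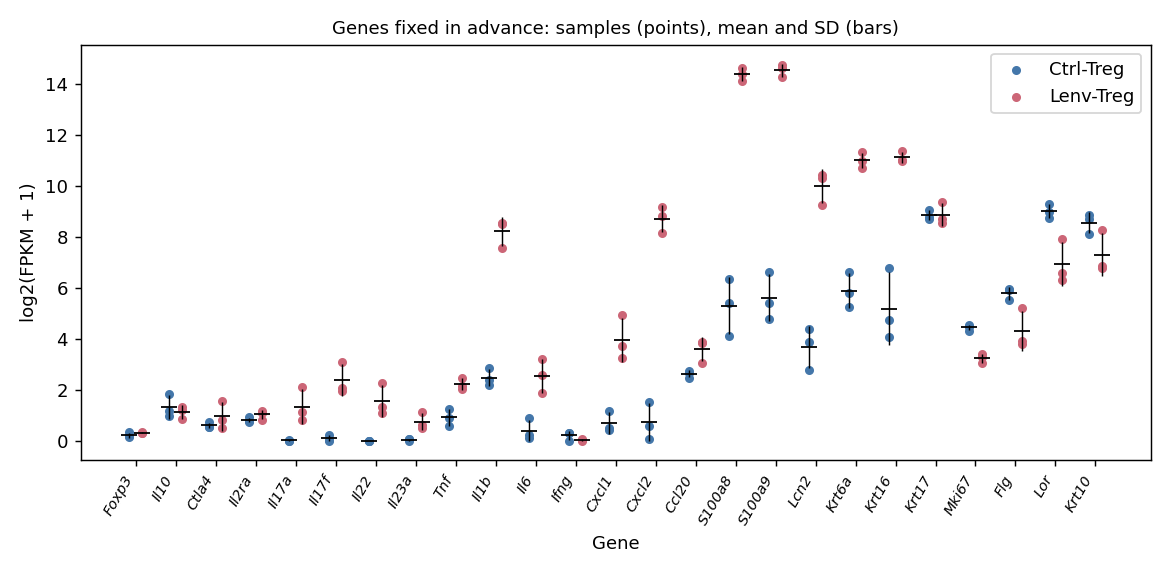
The 25 genes fixed in advance, with log2(FPKM + 1) of each library as a point, group mean and SD as black bars (n = 3), Ctrl-Treg in blue and Lenv-Treg in red. S100a8, S100a9, Il1b, Cxcl2, Lcn2, Krt6a and Krt16 are far higher in all Lenv-Treg libraries, while Foxp3 and Krt17 overlap.

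Interferon response genes moved the other way. Of 30 type I interferon response genes, 0 rose and 26 fell in Lenv-Treg, 27 over the list alone (median -1.01, scaled -0.85, camera adjusted p = 1.5e-06, adjusted p = 0.49 with an estimated correlation). Irf7, a transcription factor that amplifies interferon production, fell from 63.2 ± 20.4 to 11.2 ± 0.493 FPKM (-2.35, SE 0.21, adjusted p = 0.000238), and Ifit3 (-2.23), Ifi27l2a (-1.46) and Bst2 (-1.38) fell. Of 26 interferon gamma and type 1 genes, 2 rose and 22 fell, also over the list alone (median -1.05, scaled -0.85, camera adjusted p = 2.2e-05, adjusted p = 0.43 with an estimated correlation). The interferon-induced GTPase genes Iigp1 (-2.51), Gbp3 (-1.79) and Gbp2 (-1.66) and the immunoproteasome gene Psmb8 (-0.74) fell. Ifng lay outside the filter, at 0.188 ± 0.144 FPKM in Ctrl-Treg and 0.0346 ± 0.0318 FPKM in Lenv-Treg (exact permutation p = 0.3), a ratio of 0.184 that was 0.109 without Lenv-Treg replicate 3.

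Genes of regulatory T cells and of anti-inflammatory mediators were examined next. Foxp3, the lineage factor of Tregs, lay outside the filter at 0.193 ± 0.0812 FPKM in Ctrl-Treg and 0.268 ± 0.0216 FPKM in Lenv-Treg, from 90 and 126 reads over the groups (exact permutation p = 0.3). Il10 (1.64 ± 0.892 and 1.26 ± 0.392 FPKM, adjusted p = 0.545), Ctla4 (0.550 ± 0.120 and 1.08 ± 0.836 FPKM, adjusted p = 0.287, a fold of 1.96 that was 1.11 without Lenv-Treg replicate 3) and Il2ra (0.788 ± 0.115 and 1.1 ± 0.263 FPKM, adjusted p = 0.159) did not pass. Of the 20 members of the Treg list, 6 rose and 1 fell, also over the list alone (median 0.23, scaled 0.38, TPM 0.03, 0.43 after quantile normalization, camera adjusted p = 0.00064, adjusted p = 0.43 with an estimated correlation). The median was 0.13 without Lenv-Treg replicate 3, and fry did not pass (adjusted p = 0.13). The members with the smallest p were Areg (2.63) and Entpd1 (1.17), which other cell types also express. Capg rose by 0.68, a call that ended without any 1 of 4 libraries (adjusted p up to 0.103) and after rescaling to TPM (0.39, adjusted p = 0.0736), and Tgfb1 did not pass (0.37, adjusted p = 0.0687). Of 28 anti-inflammatory mediators and inhibitors, 16 rose and 4 fell, 17 and 5 over the list alone (median 0.48, scaled 0.69, TPM 0.21, camera adjusted p = 4.9e-06, adjusted p = 0.27 with an estimated correlation). Il1rn, the IL-1 receptor antagonist, rose 3.56-fold, Nfkbia 2.9-fold and Hmox1 2.75-fold. The list shares Il1r2 with the neutrophil list, Il36rn with the keratinocyte response list, and Dusp1 and Zfp36 with the immediate early list. It shares Nfkbia and Tnfaip3 with the TNF, IL-1 and NF-kB list, and Socs1 and Cd274 with the interferon gamma list. Il10, Ebi3, Tgfb1 and Entpd1 are also on the Treg list. Neutrophil (20 of 23), macrophage (19 of 31) and immediate early genes (11 of 28) rose in the same libraries. So did keratinocyte response genes (30 of 32) and TNF, IL-1 and NF-kB genes (25 of 34). Anxa1 rose by 0.44, a call that ended without any 1 of 5 libraries (adjusted p up to 0.126), after rescaling to TPM (0.15, adjusted p = 0.291) and after quantile normalization (0.22, adjusted p = 0.166).

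Neutrophil and macrophage markers were higher in Lenv-Treg. Of 23 neutrophil genes 20 rose and 1 fell, also over the list alone (median 2.46, scaled 2.58, camera adjusted p = 1.6e-18, adjusted p = 0.19 with an estimated correlation). Retnlg rose from 1.89 ± 0.489 to 256.3 ± 94.7 FPKM, and the stefin genes Stfa2 and Stfa2l1 rose 45.6-fold and 98.9-fold. Asprv1, which epidermis also expresses, did not pass (-0.73, adjusted p = 0.137). Of 31 monocyte and macrophage genes 19 rose and 2 fell, 20 and 2 over the list alone (median 0.75, scaled 0.96, camera adjusted p = 7.6e-13, adjusted p = 0.27 with an estimated correlation). Lyve1 (2.12) and Trem2 (1.84) rose, C1qb did not pass (0.30, adjusted p = 0.147), and Lyz2 rose by 0.75, a call that ended without Lenv-Treg replicate 2 or 3 (adjusted p = 0.0526 and 0.058). Of 11 mast cell genes 3 rose and 1 fell, also over the list alone (median 0.26, scaled 0.45, camera adjusted p = 0.007, adjusted p = 0.49 with an estimated correlation). The median was 0.07 without Lenv-Treg replicate 3, 0.12 without Ctrl-Treg replicate 2, 0.41 without Lenv-Treg replicate 1 and -0.01 after rescaling to TPM, and fry did not pass (adjusted p = 0.081). Hdc (3.44), which is also on the neutrophil list, and Fcer1a (2.62) rose, while the mast cell proteases Mcpt4 and Cma1 did not pass (adjusted p = 0.412 and 0.318).

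Lymphoid and dendritic cell lists did not pass. Members higher and lower were 2 and 4 of 15 for T cells (median -0.17, camera adjusted p = 0.89), 1 and 1 of 5 for gamma delta T cells (0.38, adjusted p = 0.43), and 0 and 5 of 14 for NK and cytotoxic cells (-0.12, adjusted p = 0.82). They were 0 and 2 of 5 for B and plasma cells (0.00, adjusted p = 0.73) and 2 and 12 of 27 for dendritic cells and MHC class II (-0.29, adjusted p = 0.81). For the dendritic cell list the median and mean were negative while camera, which compares with other genes, pointed up. Leaving out 1 library moved the medians to between -0.30 and -0.09 for T cells, -0.20 and 0.00 for NK cells and -0.18 and 0.14 for B cells. The gamma delta T cell median was 0.20 without Lenv-Treg replicate 3 and 0.24 without Ctrl-Treg replicate 2. Over the lists alone, the counts of members were the same except for 0 and 4 in the NK list and 1 and 2 in the B cell list.

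Hair follicle and pigment cell genes were far lower in Lenv-Treg. Of 39 hair follicle and hair shaft genes 0 rose and 38 fell, also over the list alone (median -4.01, scaled -3.91, camera adjusted p = 8.3e-17, adjusted p = 0.37 with an estimated correlation). They took 0.529% to 1.04% of reads in Ctrl-Treg and 0.0357% to 0.0641% in Lenv-Treg. Krt71, a keratin of the inner root sheath, fell from 830.5 ± 322.6 to 1.94 ± 2.65 FPKM (-8.42, SE 0.60, adjusted p = 0.000105). Of the 12 largest decreases, the others were Krt25 (-7.87), Krt27 (-7.58), Krt77 (-6.94, a member of the epidermal differentiation list, not of the hair list), Krt73 (-6.92), Krt35 (-6.73), Tchh (-6.63), Krt85 (-6.59), Prr9 (-6.53), Krt28 (-6.36), Krtap8-1 (-6.08) and Krtap7-1 (-5.70). Prr9 and Krtap7-1 are not on the hair list either. Adjusted p was at most 0.00014 for the 12 largest decreases. Without Lenv-Treg replicate 2 the ratio of Lenv-Treg to Ctrl-Treg mean FPKM fell further by over 1.5 times for 9 of the 12, for Krt71 to 0.000502 against 0.00234. Krt79 fell by 1.12, a call that ended without any 1 of 4 libraries (adjusted p up to 0.0888) and after median-ratio scaling (adjusted p = 0.0725). Of 9 melanocyte genes 0 rose and 8 fell, also over the list alone (median -2.12, scaled -2.03, camera adjusted p = 2.6e-05, adjusted p = 0.39 with an estimated correlation). The pigment genes Dct (-4.28), Tyrp1 (-3.90), Pmel (-3.81) and Tyr (-2.12) fell.

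Epidermal genes split. Of 44 differentiation and barrier genes 14 rose and 18 fell, also over the list alone (median -0.29, scaled -0.08, camera adjusted p = 0.33), with a negative median and mean while camera pointed up; the list passed after rescaling to TPM (median -0.58, adjusted p = 0.0105). Its median was -0.48 without Lenv-Treg replicate 1, -0.45 without Ctrl-Treg replicate 2 and -0.11 without Lenv-Treg replicate 3. Krt77, an epidermal keratin, had the largest decrease in the list, from 301.8 ± 98.7 to 1.38 ± 0.256 FPKM (-6.94, adjusted p = 1.49e-05). Lor fell from 524.5 ± 99.5 to 139.2 ± 89.1 FPKM (adjusted p = 0.00545), a ratio of 0.265 that was 0.168 without Lenv-Treg replicate 1. Flg fell by 1.47 (adjusted p = 0.0148), a call that ended without Lenv-Treg replicate 2 or 3 (adjusted p = 0.0551 and 0.0508) and with no filter on low values (adjusted p = 0.0505). Krt10 fell by 1.25 (adjusted p = 0.0419), a call that ended without any 1 of 4 libraries (adjusted p up to 0.134), after median-ratio scaling (adjusted p = 0.0849) and with no filter (adjusted p = 0.108). Without Lenv-Treg replicate 1 the ratio of Lenv-Treg to Ctrl-Treg mean FPKM was 0.249 against 0.388 for Flg and 0.292 against 0.461 for Krt10. Lce3b rose from 0.495 ± 0.391 to 129.5 ± 36.8 FPKM, and Krtdap (adjusted p = 0.106) and Krt1 (adjusted p = 0.99) did not pass. Of 12 basal keratinocyte genes 7 rose and 2 fell, also over the list alone (median 0.48, scaled 0.67, TPM 0.23, camera adjusted p = 0.0013, adjusted p = 0.27 with an estimated correlation). Krt14 rose 5.75-fold, Krt5 1.88-fold and Itga6 1.86-fold, and Krt15, which also marks the hair follicle bulge, fell by 3.72.

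Cell cycle genes were lower in Lenv-Treg: of 38 members 0 rose and 29 fell, also over the list alone (median -0.59, scaled -0.42, TPM -0.90, camera adjusted p = 5.6e-06, adjusted p = 0.49 with an estimated correlation). Hair follicle genes, which mark a tissue that proliferates during hair growth, fell in the same libraries (38 of 39, median -4.01), and the values do not say in which cells cell cycle genes were lower. Mki67, the Ki-67 gene, fell from 21.2 ± 1.71 to 8.65 ± 1.19 FPKM (-1.21, SE 0.12). Foxm1 (-1.07) and Pcna (-0.58) fell, and Ube2c did not pass (adjusted p = 0.483). Of 27 glycolysis and hypoxia genes 21 rose and 0 fell, 21 and 1 over the list alone (median 0.80, scaled 1.02, TPM 0.52, camera adjusted p = 3.5e-15, adjusted p = 0.19 with an estimated correlation). The glucose transporter gene Slc2a1 rose 7.64-fold, Hif1a 2.58-fold and Eno1 2.24-fold. Neutrophil genes (20 of 23, median 2.46) and macrophage genes (19 of 31, median 0.75) rose in the same libraries. The values do not say in which cells glycolysis and hypoxia genes were higher. Tpi1 rose by 0.53, a call that ended without any 1 of 5 libraries (adjusted p up to 0.154), after rescaling to TPM (0.24, adjusted p = 0.274) and after quantile normalization (0.29, adjusted p = 0.28). Of 37 genes of oxidative phosphorylation 1 rose and 1 fell, and 0 and 0 over the list alone (median -0.01, scaled 0.20, camera adjusted p = 0.051), and this list passed in 8 other settings, among them median-ratio scaling (adjusted p = 0.00437). Its median was between -0.09 and 0.05 with 1 library left out.

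**Figure D3:**
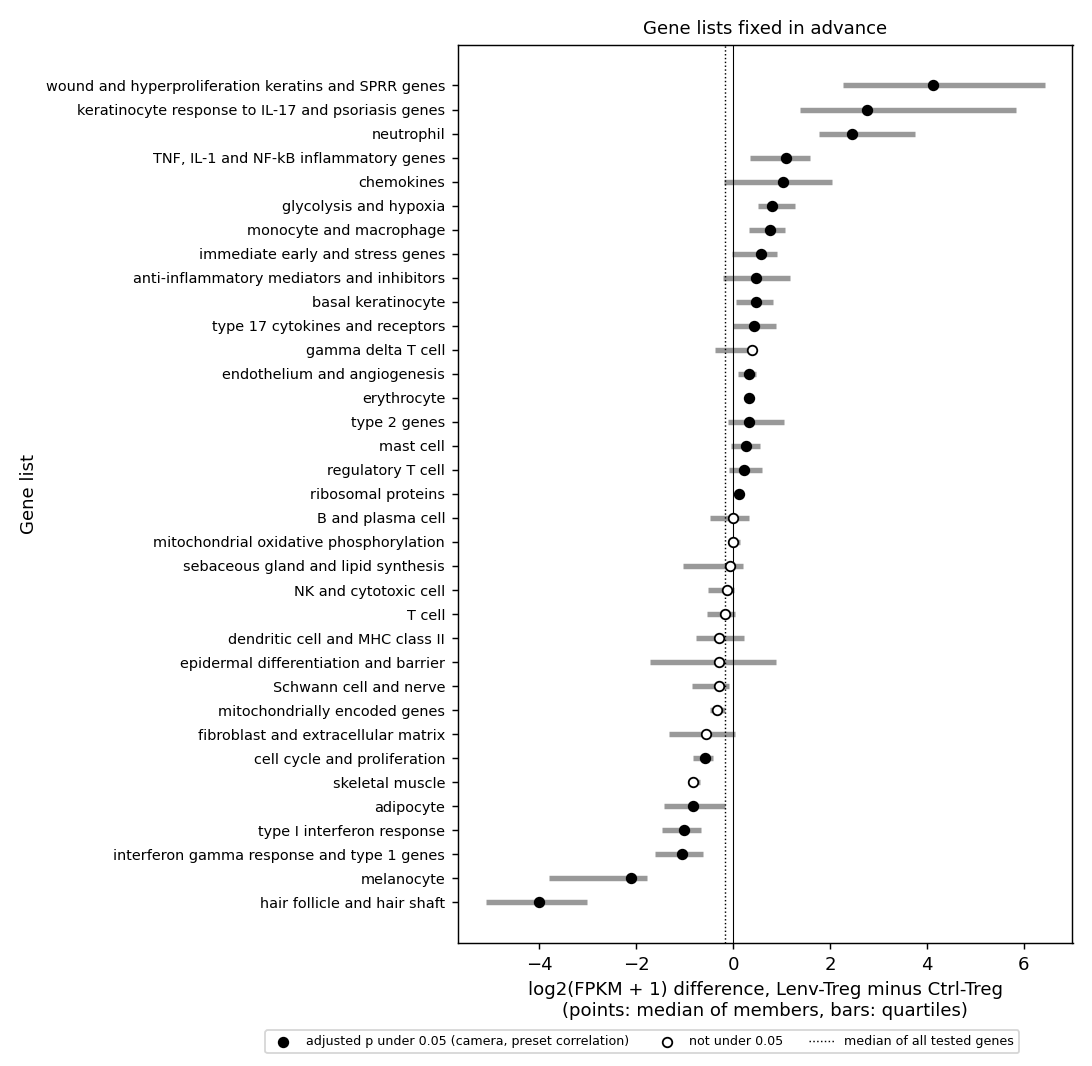
Median (points) and quartiles (bars) of the log2(FPKM + 1) differences, Lenv-Treg minus Ctrl-Treg, for the 35 lists, filled where camera passed with the preset correlation. Medians run from -4.01 for hair follicle genes to 4.12 for wound keratins and SPRR genes, and the dotted line marks the median of all tested genes, -0.17.

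Among other tissue lists, 1 adipocyte gene rose and 12 of 21 fell, also over the list alone (median -0.84, scaled -0.63, camera adjusted p = 0.013, adjusted p = 0.52 with an estimated correlation). Adrb3 (-2.44), Car3 (-1.43) and Acaca (-1.20) fell. Cfd fell by 0.84, a call that ended without any 1 of 4 libraries (adjusted p up to 0.0734) and after median-ratio scaling (adjusted p = 0.0803). Of 27 endothelial and angiogenesis genes 6 rose and 1 fell, 4 and 0 over the list alone (median 0.33, scaled 0.50, TPM 0.07, camera adjusted p = 2.6e-05, adjusted p = 0.49 with an estimated correlation). The median was 0.19 without Ctrl-Treg replicate 3, and fry did not pass (adjusted p = 0.19). Vegfa rose 2.18-fold and Pgf 2.24-fold, whereas Plvap (adjusted p = 0.0732) and Pecam1 (adjusted p = 0.0756) did not pass. Of 6 erythrocyte genes none passed alone (median 0.32, scaled 0.52, TPM 0.04, and 0.55 without Lenv-Treg replicate 1), among them Hbb-bs, Hba-a1, Alas2 and Hbb-bt. The list passed camera (adjusted p = 0.024, adjusted p = 0.54 with an estimated correlation) but not without Lenv-Treg replicate 3 (median 0.09, adjusted p = 0.132) or after median-ratio scaling (adjusted p = 0.0524) or quantile normalization (adjusted p = 0.144).

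Fibroblast and matrix genes (3 higher and 16 lower of 30, median -0.57, adjusted p = 0.16), skeletal muscle (3 and 3 of 27, -0.83, adjusted p = 0.43), sebaceous gland (5 and 14 of 31, -0.07, adjusted p = 0.91) and Schwann cell and nerve (1 and 6 of 12, -0.29, adjusted p = 0.26) did not pass camera. Over the lists alone the counts were 3 and 16, 1 and 3, 6 and 14, and 1 and 6. The fibroblast list passed after median-ratio scaling (median -0.38, adjusted p = 0.0405), after quantile normalization (-0.55, adjusted p = 0.0017), with no filter on low values (-0.57, adjusted p = 0.0487) and without Lenv-Treg replicate 1 (-0.68, adjusted p = 0.0345). The sebaceous median was between -0.45 without Ctrl-Treg replicate 2 and -0.03 without Lenv-Treg replicate 2. The muscle list passed without Ctrl-Treg replicate 3 (-1.22, adjusted p = 0.00277), which had 0.916% of reads in muscle genes against 1.74% and 2.72% in the other Ctrl-Treg libraries. Without Ctrl-Treg replicate 2 its median was -0.39 (adjusted p = 0.702), and it passed after quantile normalization (-0.94, adjusted p = 0.0186).

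Of lists on RNA handling, 11 of 28 immediate early and stress genes rose and 3 fell, 14 and 3 over the list alone (median 0.57, scaled 0.78, TPM 0.29, camera adjusted p = 4.9e-06, adjusted p = 0.43 with an estimated correlation), and fry did not pass (adjusted p = 0.069). Ier3 rose by 1.86 and Ppp1r15a by 0.94, Hspb1 did not pass (adjusted p = 0.488), and Fos rose by 1.23, a call that ended without any 1 of 4 libraries (adjusted p up to 0.0662) and after quantile normalization (adjusted p = 0.0508). Of 51 ribosomal protein genes none passed alone, including Rplp1, Rpl32, Rps2 and Rps9, while the list passed camera (median 0.11, scaled 0.32, adjusted p = 0.00063, adjusted p = 0.77 with an estimated correlation) and pointed down after quantile normalization (median -0.12). Its median was between -0.01 without Lenv-Treg replicate 3 and 0.25 without Ctrl-Treg replicate 3, was -0.18 after rescaling to TPM, and fry did not pass (adjusted p = 0.66). None of 13 mitochondrially encoded genes passed (median -0.34, -0.21 without Ctrl-Treg replicate 2, camera adjusted p = 0.51, and 0.00224 after quantile normalization), and these took 2.52% to 3.7% of reads in Ctrl-Treg and 2.14% to 2.83% in Lenv-Treg. In all, 23 of the 35 lists passed camera, 17 up and 6 down, 20 passed fry, and 0 passed camera with an estimated correlation (8 at an unadjusted p under 0.05).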

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

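Of the settings below, voom on recovered reads was chosen after the data were seen, and the rest before. Main counts were 5821 genes, 1532 higher and 4289 lower. Median-ratio scaling gave 2417 higher and 2417 lower, rescaling to TPM 8917 (947 and 7970), and quantile normalization 2232 higher and 2304 lower. The shift of all genes (median -0.17) became 0.00, -0.44 and -0.01. Requiring at least 2-fold left 1340 (524 and 816), by construction. Leaving out 1 library gave 3932 to 5285 genes, 1152 to 1447 higher and 2780 to 3900 lower, with fewer samples in each fit. The lowest was without Lenv-Treg replicate 2 (2780 lower). Voom gave 5870 genes, of which 5648 were shared with the main calls in direction. In none of these fits did a shared call change direction.

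The samples were not treated as paired, since the labels state no pairing and not every same-number correlation was above 0.1: same-number deviations correlated at 0.196, -0.011 and 0.328, and 4 of 6 samples correlated best with their own number, so whether numbers mark pairs stays unknown. With the replicate block, 5907 genes passed (1637 higher, 4270 lower) and 24 lists.

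The 23 lists past the threshold became 0 with an estimated correlation (the cause was not tested), 20 with fry, and 22 to 25 in every other setting (22 to 25 with 1 library left out). The type 2 list lost the call although its estimated correlation, 0.0073, lay below the preset 0.01. For that list a higher correlation does not account for the loss. In the other lists that passed, the estimate lay above the preset value, from 0.053 for type 17 genes to 0.92 for ribosomal proteins. It was 0.24 for the keratinocyte response list and 0.7 for the hair list. Ribosomal proteins pointed down after quantile normalization (median -0.12), and fry put the gamma delta T cell list down (median 0.38), where the main test did not pass. The cause was not tested. Oxidative phosphorylation, fibroblast, muscle, epidermal differentiation and mitochondrially encoded lists passed only in some alternatives. The erythrocyte list was lost after median-ratio scaling, after quantile normalization, without Lenv-Treg replicate 3 and with fry. Fry also lost the regulatory T cell, mast cell, endothelium, immediate early and ribosomal lists, and the Schwann cell and fibroblast lists passed with it. Of 123 named genes tested, 98 passed; none reversed in any setting, and 9 lost the call when some library was left out. With no filter on low values the same 9 did (Anxa1, Capg, Lyz2, Cfd, Krt79, Tpi1, Fos, Flg and Krt10, adjusted p = 0.0505 to 0.108), and 3 did under each of the 3 scalings. Depth was similar in all libraries and limits genes of few reads, such as Il17a, Il22, Il23a, Foxp3 and Ifng.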

Other observations

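The gene groups in the first 2 paragraphs, and the tests of explanations below, were chosen after the results were seen, except the count of other splits; median-ratio scaling itself was planned, and its use as a test was not. Most Hedgehog pathway and dermal papilla genes were lower in the libraries labelled Lenv-Treg, and no list test was run on these groups. Of 12 Hedgehog pathway genes 11 fell and 1 rose (median -1.29, scaled -1.18). Gli1, a transcription factor and target of the pathway, fell from 19.4 ± 2.37 to 0.764 ± 0.248 FPKM, and Shh (-3.25) and Ptch1 (-2.40) fell, while Gas1 rose by 1.06. Of 11 dermal papilla genes 9 fell and 0 rose (median -1.34, scaled -1.22), among them Wif1 (-2.88), Corin (-2.42) and Bmp4 (-2.11).

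Of 18 clock and clock output genes 9 fell and 2 rose (median -0.43, scaled -0.28). The output genes Dbp (-2.02), Hlf (-1.18) and Tef (-1.01) and the clock repressor gene Nr1d1 (-1.02) fell, while Per1 (adjusted p = 0.177), Per2 (adjusted p = 0.595) and Cry1 (adjusted p = 0.969) did not pass. The time of day of collection was not used here. Of 13 glucocorticoid-responsive genes 11 rose and 0 fell (median 0.78, scaled 0.99), among them Fkbp5 (1.32), Zbtb16 (1.14) and Tsc22d3 (0.78). Of 10 tested Skint genes, a family expressed in keratinocytes and thymus, 7 fell and 0 rose (median -1.42, scaled -1.26), with Skint9 falling from 40.0 ± 3.88 to 3.24 ± 3.92 FPKM.

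The real split gave 5821 genes past the threshold in limma (7147 at an unadjusted p under 0.05), and the highest of the other splits gave 0 (705 unadjusted); with 10 splits, of which 1 gave as many genes, the share cannot go under 0.05.

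Inflammatory and keratinocyte stress genes were higher in the libraries labelled Lenv-Treg, a direction opposite to the one the series title names. A single mislabelled library is argued against, since the highest correlation between groups was 0.939 and the lowest within groups 0.984. More neutrophils alone are argued against for the wound keratin and SPRR genes, since the lower quartile of that list was 2.27, and they stay open for the keratinocyte response, cytokine, chemokine and anti-inflammatory lists. An exchange of all labels between the groups cannot be told apart from a treatment effect, because no gene marks the treatment; it would turn the direction of the 30 keratinocyte response genes that rose. An effect of the treatment, or a difference in disease stage or severity between the mice, may also account for the pattern and was not tested.

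Hair follicle genes were lower in the same libraries. A few genes taking more of the reads is argued against, since the list's median stayed at -3.91 after median-ratio scaling. Dilution by other tissue is argued against, since the upper quartile of the hair list was -3.02 and the lowest lower quartile of the fibroblast, endothelium, nerve and sebaceous lists was -1.33. Whether a loss of the growing lower follicle spared the stem cell niche cannot be told here. The bulge genes overlap the hair list, and the values do not say in which cells they were lower. Of 11 bulge genes 9 fell and 0 rose (median -1.16). Lgr5 and Sox9 among them are also on the hair list. Krt15 (-3.72), Lhx2 (-3.28), Lgr6 (-1.84), Lrig1 (-1.18), Cd34 (-1.02), Tcf7l1 (-0.81) and Bmp6 (-0.71) are not on that list and fell too. Nfatc1 (-0.14, adjusted p = 0.421) and Col17a1 (0.11, adjusted p = 0.506) did not pass, and sparing of the niche stays open. A difference in hair cycle stage between the mice, in the site of sampling or by treatment stays open as a hypothesis and may account for the pattern.

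Interferon response genes were lower. A few genes taking more of the reads is argued against by a type I list median of -0.85 after scaling, with an upper quartile of -0.5. Reads shared within multigene families are argued against for 15 members of the type I list outside such families, of which 14 fell and 0 rose. Their median was -0.97 and their upper quartile -0.83. These members were picked after the list had been seen to fall. They add no separate support, and shared reads stay open for members within families. Fewer leukocytes overall are argued against by a median of 0.36 for 12 pan-leukocyte genes, with a lower quartile of 0.23, though fewer cells of 1 leukocyte type stay open. Lower interferon signalling in the libraries labelled Lenv-Treg may be biological, as a hypothesis found in these data and not itself tested. The tests of the other explanations used the same data.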
